A study of Mus musculus with 12 samples.

How the data were processed

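RNA was sequenced in 12 libraries of mouse nerve, 3 each of whole sciatic nerve, sciatic RiboTag, whole vagus nerve and vagus RiboTag. Per the labels' protocols, the mice carried Mpz-Cre and a RiboTag allele that adds an HA tag to RPL22 in Mpz-expressing cells, nerves were dissociated with liberase, the epineurium was removed from the sciatic nerve only, and tagged polyribosomes were pulled down with an antibody to HA. Per the labels, libraries were made with an Illumina kit and run on a HiSeq, and the mice were untreated. The labels do not say whether libraries of a group came from separate animals.

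The authors deposited 1 table of raw read counts per gene, with whole numbers for 46078 Ensembl genes in 12 columns. Per the submitters' processing notes, the tools were bcl2fastq, STAR 2.5.1a1, featureCounts 1.4.6-p5 of Subread and Salmon 0.8.2, with no role or order given. Genome build, annotation and strand setting are not given in the sources used here. For positions, gene types, GC content and transcript lengths, gene identifiers were matched to GENCODE M21, which held 98.2% of them, and 270 gene symbols stood for more than 1 identifier. Every column belonged to a sample of the labels. Columns of whole sciatic nerve and of both vagus groups carry an index tag and no replicate number, and are numbered here in the order of the table. No library was a copy of another, checked on the differences between their counts.

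Counts were fitted in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood, robust, TMM scaling), with all 12 libraries and 4 groups in 1 fit and 8 residual degrees of freedom. The filter filterByExpr, with a minimum count of 10, kept 18997 genes. The 5 comparisons were RiboTag against whole in each nerve, the difference between these enrichments, and vagus against sciatic nerve in RiboTag and in whole libraries. P-values were adjusted by BH over all tested genes of a comparison, and a gene passed with an adjusted p under 0.05. Levels are CPM scaled by TMM, as mean ± SD of 3 libraries, and log2 fold changes are given ± SE with a prior count of 0.125. That SE is the absolute log2 fold change divided by the square root of the quasi-likelihood F, and is approximate. Where a group had no count, a bound on the fold took 3 counts per library as the floor. Where it had 1 to 3 counts in all, a ratio with a 95% counting interval is given.

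For shares of counts, differences between groups were tested by exact permutation of the library labels, two-sided. Depth was 10109014 to 19359571 counts per library, and intervals and bounds at low counts give the precision this allows.

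There were 29 gene lists of cell types and processes, assembled from general knowledge before the data were examined, and tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, BH-adjusted over the 145 tests. Alongside the counts of members that passed over all genes, counts after BH adjustment within the list are given as adjusted over the list alone. A list of 32 hepatocyte genes and a list of 10 mesothelium genes were added after the data were seen, and are given as summed CPM with no test.

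Genes named in the text follow a rule fixed before the data were examined. It takes Mpz and Rpl22. It takes the 8 genes in each direction with the largest log2 fold change among those that passed, with no overlap between the 3 libraries of each group and a mean of at least 10 CPM in the higher group, and 4 per direction with no condition on overlap for the difference of enrichment. It takes up to 3 tested members with the highest mean CPM of each list, all members of the myelinating subtype list, and all passing members of a list with 5 or fewer. Not every gene the rule names is printed. Other genes, such as list members that moved against their list, Ddx3y and Gpm6a, were chosen after their values were seen.

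Alternatives set beforehand were DESeq2 size factors, upper-quartile scaling and library size alone. Further ones were the DESeq2 1.42.0 Wald test, limma-voom with sample quality weights, no filter on low counts, a stricter filter (CPM above 1 in at least 6 libraries), mitochondrially encoded genes left out, an absolute log2 fold change of at least 1, each library left out in turn, and the 6 compared libraries alone. For the vagus, a replicate block by shared index tag was fitted. For lists, camera with an estimated correlation and fry were run, and ranges of adjusted p for lists cover the camera alternatives alone. Added after the data were seen were an offset per gene and library for GC content and transcript length (loess, span 0.4, 18894 genes) and a fit of protein-coding genes alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

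The fit was tested on simulated data with 2-fold and 4-fold changes in about 190 genes. Depending on the comparison, 6.32% to 23.2% of the 2-fold and 49.5% to 64.2% of the 4-fold changes passed, with 1 to 6 false calls. The recovery of 4-fold changes missed a target of 60% set beforehand in 3 of the 5 comparisons, so the test was then judged on false calls and on the size of the fitted changes. The simulated groups were otherwise alike in every gene, unlike the real ones. With a simulated GC bias and no true change, 3353 genes passed without the offset and 0 with it. That bias was linear in GC content, which the offset is built to remove. The result does not show whether the offset also removes true differences. Of 2 simulated lists of 19 genes, camera passed the one that moved and not the one that stayed.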

Results

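The data were read counts per gene from 12 mouse RNA sequencing libraries, 3 from each of 4 groups. RiboTag libraries held RNA that came down with ribosomes carrying a hemagglutinin (HA) tag on the protein RPL22, which Mpz-Cre switches on in cells that express the myelin gene Mpz. Whole libraries held RNA of the dissected nerve with no pulldown, and the epineurium was removed from the sciatic nerve only. Each kind was made from sciatic nerve, which serves the leg, and from vagus nerve, which links the brainstem with the inner organs. Totals ran from 10109014 counts in a sciatic RiboTag library to 19359571 in a whole vagus library. Genes with at least 1 count averaged 25169 in whole sciatic, 16998 in sciatic RiboTag, 24549 in whole vagus and 20449 in vagus RiboTag libraries. Nothing in the labels says that libraries of a group came from separate animals, so the p-values measure only the spread between these samples.

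Mpz, the main structural protein of peripheral myelin, took 3.17 ± 0.174% of counts in sciatic RiboTag libraries and 1.29 ± 0.291% in whole sciatic libraries (mean ± SD, n = 3 in each group). In the vagus it took 0.565 ± 0.179% of RiboTag and 0.0239 ± 0.0115% of whole counts. Mitochondrially encoded mRNAs took 1.36% and 1.66% of whole sciatic and whole vagus counts, against 0.0731% and 0.136% of the corresponding RiboTag counts. Genes of cytosolic ribosomal proteins took 0.398% in whole sciatic, 0.502% in sciatic RiboTag, 0.975% in whole vagus and 0.674% in vagus RiboTag libraries. The 10 most counted genes of a library held 27.0%, 18.9%, 8.56% and 18.2% in the same order. With mitochondrially encoded genes left out of the total, 2 differences between RiboTag and whole sciatic libraries changed sign, that of the 10 most counted genes from -8.13 to 8.94 percentage points and that of ribosomal proteins from 0.104 to -0.00406, and the difference of the 10 most counted genes between whole vagus and whole sciatic went from -18.5 to -1.67. In a two-sided exact permutation test of each of these 4 shares, 3 libraries against 3 allow 20 assignments and no p under 0.1, and p was 0.1 in 14 of the 16 tests. The exceptions were ribosomal protein genes in RiboTag against whole sciatic nerve (exact permutation p = 0.2) and the 10 most counted genes in vagus against sciatic RiboTag (exact permutation p = 0.7).

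Several measured facts set groups apart besides their labels. Mitochondrial ribosomal RNA took 19.9 ± 1.92% of whole sciatic counts, 0.120% of sciatic RiboTag, 0.781% of whole vagus and 0.213% of vagus RiboTag counts. Yam1 and Lars2, whose loci hold sequence resembling ribosomal RNA, took 6.13% and 2.23% of vagus RiboTag counts, and 0.0545% and 0.00370% of whole sciatic counts. Transcripts of a hepatocyte list, added after the data were seen, took 1.31 ± 1.09% of whole vagus counts and 0.0118% of whole sciatic counts. Skeletal muscle genes took 0.237 ± 0.225% of whole vagus and 0.0802 ± 0.0577% of vagus RiboTag counts, against 0.00246% and 0.000356% in the sciatic groups. Xist, the RNA of X inactivation, lay between 0 and 0.404 CPM (counts scaled to library size) in the 3 sciatic RiboTag libraries, where the Y-linked gene Ddx3y lay between 100.2 and 149 CPM. Ddx3y was under 1 CPM in whole sciatic library 2 and whole vagus libraries 1 and 3, and lay between 20.8 and 58.4 CPM in the other 6. By Pearson correlation across genes of log CPM, libraries of a group lay between 0.936 and 0.985, and libraries of different groups between 0.658 and 0.901. The leading 3 principal components held 47.1%, 28.0% and 10.2% of the variance.

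Positions of the main genes are given in GRCm38 from GENCODE M21, as 1-based gene bodies, since the build behind the counts is not given in the sources used here and genes were matched by Ensembl identifier. Mpz (ENSMUSG00000056569) lies on chromosome 1, 171150711 to 171161130, plus strand, and Rpl22 (ENSMUSG00000028936), the gene of the tagged protein, on chromosome 4, 152325742 to 152334071, plus strand. The myelin genes Mbp (ENSMUSG00000041607), Pmp22 (ENSMUSG00000018217) and Pmp2 (ENSMUSG00000052468) lie on chromosome 18, 82475146 to 82585637, plus strand, on chromosome 11, 63128982 to 63159547, plus strand, and on chromosome 3, 10179851 to 10183929, minus strand. Plp1 (ENSMUSG00000031425), Ncam1 (ENSMUSG00000039542) and Cryab (ENSMUSG00000032060) lie on chromosome X, 136822671 to 136839733, plus strand, on chromosome 9, 49502136 to 49798925, minus strand, and on chromosome 9, 50751325 to 50756636, plus strand. All 8 are annotated as protein-coding. The strand setting of the counts is not stated, so the source of reads is uncertain for genes that overlap another gene, among them Xist and Tsix, Adamtsl1, Itgb4, Sox2, Malat1, Egfl7, Csf1r, Dhcr24, Tnnc2, Notch3, Rmrp, Gm22009, Plg, Keg1, Hoxc6, Hoxd8 and mt-Co1, and for genes with close copies, such as Hbb-bs, Tpsb2 and those of ribosomal proteins.

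The first comparison asked which transcripts were over- or under-represented on tagged ribosomes relative to the whole sciatic nerve. Mpz rose from 11439 ± 2524 CPM in whole to 38576 ± 2127 CPM in RiboTag libraries (mean ± SD, n = 3), a log2 fold change of 1.75 ± 0.35 (± SE throughout). Cryab, a small heat shock protein abundant in Schwann cells, rose by 3.34 ± 0.24 to 5494 ± 408 CPM, and Plp1, a myelin proteolipid, by 1.69 ± 0.34 to 2631 ± 366 CPM. Dcn, the matrix proteoglycan decorin of fibroblasts, fell from 2775 ± 595 to 86.2 ± 2.37 CPM, and Csf1r, the receptor that macrophages depend on, from 119 ± 32.2 to 23.5 ± 5.70 CPM. The Benjamini-Hochberg (BH) adjusted p from edgeR was 0.000735 for Mpz, 1.03e-07 for Cryab, 0.000905 for Plp1, 7.52e-09 for Dcn and 4.53e-06 for Csf1r. Of 18997 tested genes, 5066 rose and 6493 fell, against 4010 and 7904 with upper-quartile scaling and 3733 and 8251 with library size alone.

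Among 23 myelin genes, 14 rose, 1 fell and 8 did not pass, and 18 passed adjusted over the list alone. The myelin median was 1.26 (camera BH-adjusted p = 0.0167, adjusted p = 0.797 with an estimated correlation). Pmp22, a compact myelin protein, rose by 1.25 ± 0.39 (edgeR BH-adjusted p = 0.0144), while Mbp, myelin basic protein, had 0.63 ± 0.32 and did not pass (edgeR BH-adjusted p = 0.101). Pmp2, a fatty acid-binding protein of myelin, was the member that fell, by 1.58 ± 0.45 on the log2 scale (edgeR BH-adjusted p = 0.00831), and Cldn14, a claudin, rose by 2.08 ± 0.78 (edgeR BH-adjusted p = 0.0334). Of 16 Schwann lineage genes, 11 rose and none fell, with 11 passing adjusted over the list alone. The lineage median was 1.403 (camera BH-adjusted p = 0.000281, adjusted p = 0.647 with an estimated correlation). Ncam1, an adhesion molecule of non-myelinating Schwann cells, rose by 2.80 ± 0.40 from 71.7 ± 7.91 CPM, and Sox2, a transcription factor of immature Schwann cells, by 2.51 ± 0.31 from 8.35 ± 2.29 CPM. The lists these belong to did not pass, with 9 of 15 non-myelinating genes higher and 2 lower (camera BH-adjusted p = 0.109), and 2 of 10 injury and repair genes higher and 3 lower (0.893). The non-myelinating list passed without vagus whole 1 or 2 (camera BH-adjusted p = 0.0379 and 0.0153) or with the GC and length offset (0.00653, range over its alternatives 0.00653 to 0.797). Rpl22 had 0.34 ± 0.18 and did not pass (edgeR BH-adjusted p = 0.115), but passed without sciatic RiboTag 3 (0.48, 0.0342, range over its alternatives 0.0334 to 1). Pmp22 did not pass without sciatic whole 1 (1.06, edgeR BH-adjusted p = 0.062, range 0.00169 to 0.579), and Pmp2 did not without sciatic whole 3 (-1.18, 0.0764, range 0.000242 to 0.0764). Cldn14 did not pass without sciatic whole 1, 2 or 3 or RiboTag 1 or 3 (edgeR BH-adjusted p = 0.109, 0.0692, 0.0834, 0.0512 and 0.137 in this order, range 0.000171 to 0.16).

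Cholesterol synthesis genes rose in 19 of 24 cases and fell in 1, with 20 passing adjusted over the list alone. The cholesterol synthesis median was 1.43 (camera BH-adjusted p = 4.1e-05, adjusted p = 0.47 with an estimated correlation). Insig1, which holds the sterol-sensing machinery in the endoplasmic reticulum, rose by 3.23 ± 0.22 to 1231 ± 113 CPM, Hmgcs1, an early enzyme of the pathway, by 1.27 ± 0.25 to 1679.7 ± 341 CPM, and Dhcr24, a sterol reductase, by 1.61 ± 0.40 to 928 ± 85.4 CPM. Srebf2, the transcription factor that drives the pathway, fell by 0.53 ± 0.18 (edgeR BH-adjusted p = 0.0187). Genes of cytosolic ribosomal proteins rose in 36 of 79 cases and fell in 12, Rpl10, Rpl17, Rpl23a, Rpl26, Rpl30, Rpl38, Rpsa, Rps2, Rps7, Rps12, Rps20 and Uba52, with 48 passing adjusted over the list alone. The ribosomal protein median was 0.52 (camera BH-adjusted p = 0.00726, adjusted p = 0.797 with an estimated correlation), and -0.91 with an offset for GC content and transcript length, chosen after the data were seen. Mitochondrially encoded mRNAs fell in 9 of 11 cases and rose in none, with 9 passing adjusted over the list alone. The mitochondrial median was -3.75, or -3.73 with genes absent from a group at their bound (camera BH-adjusted p = 1.18e-08, adjusted p = 0.261 with an estimated correlation), where mt-Co1 went from 2627 ± 104 to 75.4 ± 20.7 CPM and mt-Cytb from 2619 ± 254 to 193 ± 44.6 CPM. Long non-coding RNAs fell in 11 of 15 cases, with 14 passing adjusted over the list alone. The non-coding RNA median was -3.42 (camera BH-adjusted p = 0.0194, adjusted p = 0.654 with an estimated correlation), and Malat1, a nuclear RNA, and Gas5, host of small nucleolar RNAs, rose by 0.95 ± 0.28 and 1.25 ± 0.19. Xist, in this list too, fell by 11.37 ± 0.94, from 448 ± 347 CPM, between libraries that differed in Ddx3y.

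Of 14 lists of other cell types, 7 were lower in sciatic RiboTag libraries and 7 did not pass. All 12 epineurial fibroblast genes fell, also adjusted over the list alone. The epineurial median was -6.36 (camera BH-adjusted p = 1.34e-08, adjusted p = 0.261 with an estimated correlation), with Pi16, a peptidase inhibitor, going from 79.4 ± 36.8 to 0.557 ± 0.228 CPM and Dpt, dermatopontin, from 49.0 ± 23.1 to 0.214 ± 0.202 CPM. All 15 macrophage genes fell, 15 adjusted over the list alone. The macrophage median was -5.37 (camera BH-adjusted p = 1.72e-08, adjusted p = 0.261 with an estimated correlation), and Lyz2, lysozyme, went from 113 ± 54.7 to 2.45 ± 1.80 CPM. Perineurial genes fell in 11 of 12 cases, 11 adjusted over the list alone. The perineurial median was -5.21 (camera BH-adjusted p = 3.89e-06, adjusted p = 0.168 with an estimated correlation), and Perp, a desmosomal protein, had no count in RiboTag libraries, at least 128-fold lower than the 38.7 ± 9.60 CPM of whole nerve. Adipocyte genes fell in 9 of 11 cases, 9 adjusted over the list alone. The adipocyte median was -7.43, or -7.21 with genes absent from a group at their bound (camera BH-adjusted p = 1.81e-05, adjusted p = 0.397 with an estimated correlation), where Adipoq, adiponectin, was at least 196-fold lower and Car3, carbonic anhydrase 3, went from 408 ± 78.9 to 2.31 ± 1.85 CPM. Endoneurial fibroblast genes fell in 10 of 14 cases, 11 passing adjusted over the list alone. The endoneurial median was -3.04 (camera BH-adjusted p = 3.57e-05, adjusted p = 0.338 with an estimated correlation), and the transcription factor gene Etv1 rose by 1.66 ± 0.20. Endothelial genes fell in 11 of 15 cases, 15 passing adjusted over the list alone. The endothelial median was -1.80 (camera BH-adjusted p = 0.0421, adjusted p = 0.797 with an estimated correlation), Pecam1 had -2.48 ± 0.41, and Egfl7, a secreted endothelial protein, and Kdr, a VEGF receptor, rose by 2.18 ± 0.34 and 1.33 ± 0.40. That list did not pass without sciatic RiboTag 3 (camera BH-adjusted p = 0.0691) or vagus RiboTag 3 (0.0532, range over its alternatives 0.0157 to 0.797). Pericyte and smooth muscle genes fell in 9 of 12 cases, 9 adjusted over the list alone. The pericyte median was -2.31 (camera BH-adjusted p = 0.0378, adjusted p = 0.647 with an estimated correlation). The lists of lymphocytes, mast cells, skeletal muscle, neurons, chromaffin cells, thyroid and erythroid cells did not pass (camera BH-adjusted p = 0.223, 0.104, 0.16, 0.125, 0.413, 0.588 and 0.424). Mast cell genes passed without sciatic RiboTag 3 (0.0473, range 0.0297 to 0.439).

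Rmrp, the RNA of RNase MRP, had 699.6 ± 337 CPM in whole sciatic nerve and no count in RiboTag libraries, at least 2317-fold lower. Rpph1, the RNA of RNase P, had 1 count in RiboTag libraries and lay 65454-fold lower (95% counting interval 11747 to 2585310). Lars2 and Gm15564, which take reads of sequence resembling ribosomal RNA, went from 33.2 ± 16.7 to 43102 ± 13510.3 CPM and from 3.42 ± 1.43 to 6831 ± 1905 CPM. Whole sciatic libraries, where Rmrp and Rpph1 were high and Lars2 and Gm15564 low, also held the 19.9% of mitochondrial ribosomal RNA. Intervals and bounds cover counting error alone, and bounds rest on a floor of 3 counts per library.

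Pmp22 and Malat1 did not pass with upper-quartile scaling or library size alone, and Hmgcs1 was 0.81 with library size alone. Cldn14 did not pass with those or with DESeq2 size factors. Mbp passed with limma-voom (0.59, limma BH-adjusted p = 0.0486) and in a fit of the 6 sciatic libraries (0.54, edgeR BH-adjusted p = 0.0234, range over its alternatives 0.0111 to 1). The GC and length offset moved Mpz to 1.10, Cryab to 1.89, Pmp2 to -2.87, Malat1 to 1.74, Mbp to 1.04 and Rpl22 to -0.46 (all passing), Pmp22 to 0.27 and Cldn14 to 1.33 (not passing), and ended the calls of the long non-coding RNA, endothelial and pericyte lists, while the mast cell and erythroid lists newly passed.

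**Figure D1:**
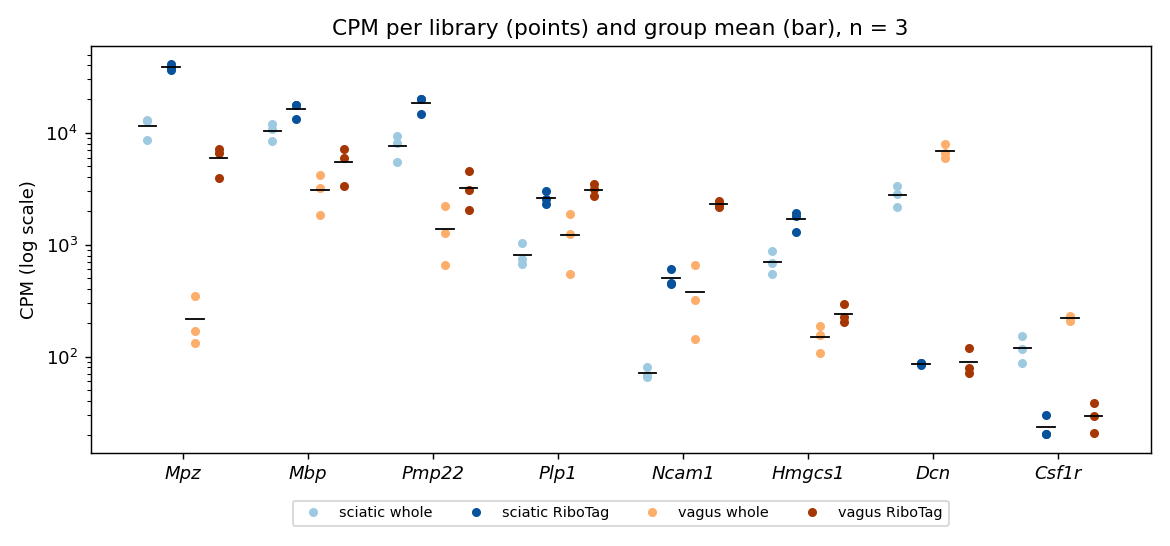
CPM (log scale) of 8 genes in each of the 12 libraries, by group, with points for libraries and bars for means (n = 3). Dcn was at most 119 CPM in the 6 RiboTag libraries and at least 2154 CPM in the 6 whole libraries.

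In the vagus nerve the same question gave a larger rise of Mpz, from 215 ± 113 CPM in whole to 5890.4 ± 1721 CPM in RiboTag libraries (mean ± SD, n = 3), or 4.78 ± 0.39. Foxd3, a transcription factor of the neural crest, rose by 6.87 ± 0.47 from 0.638 ± 0.505 to 75.3 ± 24.4 CPM, and Ncam1 by 2.61 ± 0.40 from 375 ± 265 to 2286 ± 165 CPM. Dcn fell from 6808 ± 1014 to 89.9 ± 25.6 CPM, Lyz2 from 3347 ± 1664 to 10.8 ± 8.51 CPM and Hbb-bs, a globin, from 7728 ± 3732 to 103 ± 29.1 CPM. The edgeR BH-adjusted p was 6.56e-07 for Mpz, 1.51e-07 for Foxd3, 0.000115 for Ncam1, 1.6e-08 for Dcn, 6.42e-06 for Lyz2 and 6.37e-07 for Hbb-bs. In all, 4502 genes rose and 5282 fell, against 3658 and 6276 with library size alone.

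Myelin genes rose in 19 of 23 cases and fell in 1, with 20 passing adjusted over the list alone. The myelin median was 1.92 (camera BH-adjusted p = 5.15e-06, adjusted p = 0.559 with an estimated correlation). Mbp and Pmp22 rose by 0.82 ± 0.32 and 1.23 ± 0.39 (edgeR BH-adjusted p = 0.0452 and 0.0186), and Gjb1, connexin 32 of myelinating Schwann cells and hepatocytes, fell by 2.13 ± 0.68 (edgeR BH-adjusted p = 0.0207). Of 16 Schwann lineage genes, 15 rose and none fell, 15 adjusted over the list alone. The lineage median was 2.38 (camera BH-adjusted p = 2.64e-11, adjusted p = 0.311 with an estimated correlation), with Cryab at 2.24 ± 0.23 and Plp1 at 1.33 ± 0.34. Non-myelinating Schwann genes rose in 12 of 15 cases and fell in none, 12 adjusted over the list alone. The non-myelinating median was 1.62 (camera BH-adjusted p = 0.000221, adjusted p = 0.488 with an estimated correlation), and Scn7a, a sodium channel, rose by 1.56 ± 0.31. Of the subtype genes, Pmp2 rose by 2.498 ± 0.69 at 0.996 ± 0.895 CPM in RiboTag libraries, Adamtsl1, a secreted matrix protein, fell by 3.19 ± 0.29, and Cldn14 had -1.51 ± 0.98 and did not pass. Rpl22 rose by 0.51 ± 0.18 (edgeR BH-adjusted p = 0.0278), but not without vagus RiboTag 2 (0.44, 0.0881, range over its alternatives 0.00685 to 1). Col9a2, a collagen chain, and Lrrc4b, a synaptic adhesion protein, rose by 6.18 ± 0.45 and 5.62 ± 0.47, and Rn7sk, a nuclear RNA that restrains transcription elongation, by 6.73 ± 0.48 to 17.7 ± 0.390 CPM.

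Some of these calls changed with 1 library left out. Mbp did not pass without sciatic whole 1, 2 or 3, sciatic RiboTag 1, 2 or 3, vagus whole 2 or 3, or vagus RiboTag 1 or 2 (edgeR BH-adjusted p = 0.0516, 0.0555, 0.0562, 0.0604, 0.0553, 0.059, 0.0804, 0.0582, 0.103 and 0.105 in this order, range over its alternatives 0.00886 to 1). Pmp22 did not pass without vagus RiboTag 1 (1.03, 0.0567, range 0.00138 to 0.0683) and was 1.85 without vagus whole 1. Pmp2 did not pass without vagus RiboTag 1 (1.68, 0.0588, range 0.000846 to 0.542), and Cldn14 passed at -6.52 without vagus RiboTag 3 (0.00199, range 0.00199 to 0.538).

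All 11 tested mitochondrially encoded mRNAs fell, also adjusted over the list alone. The mitochondrial median was -3.60 (camera BH-adjusted p = 3.42e-12, adjusted p = 0.201 with an estimated correlation), and mt-Cytb went from 5794 ± 1219 to 251 ± 85.1 CPM. Cholesterol synthesis genes rose in 8 of 24 cases and fell in 4, with a median of 0.14. Lists of cholesterol synthesis, fatty acid, ribosomal protein and long non-coding RNA genes did not pass (camera BH-adjusted p = 0.439, 0.887, 0.438 and 0.987). All 12 epineurial fibroblast genes and all 15 macrophage genes fell, 12 and 15 adjusted over the list alone (medians -5.57 and -4.71, camera BH-adjusted p = 3.97e-11 and 5.41e-13, and adjusted p = 0.168 and 0.17 with an estimated correlation). So did all 12 lymphocyte genes, 12 adjusted over the list alone. The lymphocyte median was -4.76 (camera BH-adjusted p = 0.000145, adjusted p = 0.421 with an estimated correlation). All 8 mast cell genes fell too, 8 adjusted over the list alone. The mast cell median was -6.60 (camera BH-adjusted p = 0.000122, adjusted p = 0.168 with an estimated correlation), with Tpsb2, a tryptase, going from 116 ± 13.7 to 0.464 ± 0.649 CPM. All 6 erythroid genes fell, 6 adjusted over the list alone. The erythroid median was -6.23 (camera BH-adjusted p = 3.32e-07, adjusted p = 0.281 with an estimated correlation). Endothelial genes fell in 12 of 15 cases, 12 adjusted over the list alone. The endothelial median was -2.50 (camera BH-adjusted p = 0.00174, adjusted p = 0.559 with an estimated correlation), with Pecam1 at -2.82 ± 0.40. Adipocyte genes fell in 9 of 11 cases, 9 adjusted over the list alone. The adipocyte median was -3.40 (camera BH-adjusted p = 0.0233, adjusted p = 0.68 with an estimated correlation), with Car3 at -3.01 ± 0.58. Endoneurial fibroblast genes fell in 8 of 14 cases and rose in 5, 14 passing adjusted over the list alone. The endoneurial median was -1.29 (camera BH-adjusted p = 0.00368, adjusted p = 0.439 with an estimated correlation). Gsn, gelsolin, had -1.47 ± 0.25 and Apod, apolipoprotein D, -2.82 ± 0.34, while Etv1, Abca8a, Col1a1, Col1a2 and Col15a1 rose. Perineurial genes fell in 9 of 12 cases, 12 passing adjusted over the list alone. The perineurial median was -3.81 (camera BH-adjusted p = 0.0104, adjusted p = 0.261 with an estimated correlation), and the netrin gene Ntn4, the Wnt antagonist gene Sfrp5 and the integrin gene Itgb4 rose, Itgb4 by 2.41 ± 0.27. Msln and Krt19, which fell, belong to the mesothelium list too, so their falls cannot be assigned to perineurial cells.

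Tat, a liver enzyme, and Gc, a plasma protein made in the liver, had 1 and 2 counts in vagus RiboTag libraries and lay 15958-fold (95% counting interval 2864 to 630348) and 8363-fold lower (2315 to 69056) than in whole vagus. Both belong to the hepatocyte list, and their whole vagus levels were 356 ± 276 and 378 ± 394 CPM. That list summed to 10682, 2351 and 22739.5 CPM in whole vagus libraries 1, 2 and 3 and to between 63.3 and 93.0 CPM in vagus RiboTag libraries. A mesothelium list, also added after the data were seen, summed to between 1874 and 5310.4 CPM in whole vagus libraries and between 96.0 and 299.7 CPM in the other 9, where Gpm6a held most of it in sciatic libraries.

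Mbp, Rpl22 and Pmp22 did not pass with library size alone or without the filter on low counts, Mbp and Rpl22 not with DESeq2 size factors, Mbp and Pmp22 not in a fit of the 6 vagus libraries, and Mbp, Rpl22 and Pmp2 not with limma, and Mbp not with the stricter filter, whereas Cldn14 passed with limma. The GC and length offset moved Itgb4 to 0.94 and ended the call of Mbp (0.70).

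The next comparison asked whether the enrichment over whole nerve differed between the nerves, as the vagus enrichment minus the sciatic enrichment (3 libraries in each of the 4 groups). For Mpz the difference was 3.02 ± 0.49 (larger in the vagus, edgeR BH-adjusted p = 0.000229), whereas Mbp, Pmp22 and Plp1 had 0.19 ± 0.45, -0.02 ± 0.55 and -0.37 ± 0.47 and did not pass. Rpl22 had 0.17 ± 0.25 and did not pass. Cryab was enriched less in the vagus, by -1.10 ± 0.32 (edgeR BH-adjusted p = 0.012). Among the subtype genes, Pmp2 had 4.08 ± 0.82, Adamtsl1 -3.23 ± 0.38 and Cldn14 -3.60 ± 1.25 (edgeR BH-adjusted p = 0.00123, 1.86e-05 and 0.031). Cryab did not pass without vagus whole 1 (-0.67, edgeR BH-adjusted p = 0.0758) or RiboTag 1 (-0.90, 0.0591, range over its alternatives 0.00367 to 0.763). Cldn14 did not without sciatic whole 1, 2 or 3, sciatic RiboTag 3, vagus whole 1 or 3, or vagus RiboTag 1 or 2 (edgeR BH-adjusted p = 0.068, 0.0503, 0.0575, 0.082, 0.0506, 0.0976, 0.0681 and 0.0539 in this order, range 0.000466 to 0.0976), and was -8.60 without vagus RiboTag 3. The difference was positive and passing for 4480 genes and negative and passing for 4172, against 5486 and 3208 with upper-quartile scaling.

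For cholesterol synthesis genes the difference was negative in 16 of 24 cases and positive in 1, Srebf2 at 1.95 ± 0.25, with 17 passing adjusted over the list alone. The cholesterol synthesis median was -1.13 (camera BH-adjusted p = 0.000738, adjusted p = 0.603 with an estimated correlation). In RiboTag against whole vagus itself, this list did not pass (median 0.14, camera BH-adjusted p = 0.439). Insig1 had -0.83 ± 0.29 (edgeR BH-adjusted p = 0.032), while Hmgcs1 and Dhcr24 had -0.59 ± 0.34 and 0.05 ± 0.55 and did not pass. Insig1 did not pass without sciatic whole 1 or 3, sciatic RiboTag 1 or 2, vagus whole 2 or 3, or vagus RiboTag 1 or 2 (edgeR BH-adjusted p = 0.082, 0.0537, 0.0676, 0.0597, 0.0675, 0.208, 0.0767 and 0.0695 in this order, range over its alternatives 0.00795 to 1), with -0.47 without vagus whole 3. Schwann lineage genes had a higher enrichment in the vagus in 9 of 16 cases and a lower one in 1, Cryab, with 10 passing adjusted over the list alone. The lineage median was 0.93 (camera BH-adjusted p = 0.0477, adjusted p = 0.797 with an estimated correlation). The list did not pass without sciatic whole 2, sciatic RiboTag 1, 2 or 3, vagus whole 2 or vagus RiboTag 2 (camera BH-adjusted p = 0.0656, 0.0715, 0.0696, 0.0598, 0.0689 and 0.0891 in this order, range 0.0012 to 0.797). Perineurial genes were higher in 5 of 12 cases, 5 adjusted over the list alone. The perineurial median was 1.36 (camera BH-adjusted p = 0.00806, adjusted p = 0.261 with an estimated correlation), with Itgb4 at 2.37 ± 0.37, Ntn4 at 7.17 ± 0.47, Perp at 7.17 ± 1.35, Sfrp5 at 2.52 ± 0.49 and Tenm2 at 4.06 ± 0.56. Msln and Krt19, shared with the mesothelium list, were not among these 5 but enter the list test. Adipocyte genes were higher in 7 of 11 cases, 7 adjusted over the list alone. The adipocyte median was 4.24 (camera BH-adjusted p = 0.000471, adjusted p = 0.439 with an estimated correlation), with Car3 at 4.42 ± 0.86. Erythroid genes were lower in 5 of 6 cases, 5 adjusted over the list alone. The erythroid median was -5.34 (camera BH-adjusted p = 0.000145, adjusted p = 0.37 with an estimated correlation), where Hbb-bs had -4.51 ± 0.64. Genes of cytosolic ribosomal proteins were lower in 30 of 79 cases and higher in 14, 44 passing adjusted over the list alone. The ribosomal protein median was -0.38 (camera BH-adjusted p = 0.0421, adjusted p = 0.857 with an estimated correlation), and 0.48 with the GC and length offset. This list did not pass without sciatic whole 2, sciatic RiboTag 2, vagus whole 2 or 3, or vagus RiboTag 1 or 3 (camera BH-adjusted p = 0.0724, 0.125, 0.11, 0.09, 0.101 and 0.0572 in this order, range 0.00748 to 0.856).

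Long non-coding RNAs were higher in 10 of 15 cases and lower in 2, Tug1 and Gas5, with 13 passing adjusted over the list alone. The non-coding RNA median was 3.34 (camera BH-adjusted p = 0.00922, adjusted p = 0.603 with an estimated correlation). Xist had 10.84 ± 1.08, next to the sex-linked differences between libraries given above. The 4 genes with the largest positive difference were Gm22009, Rpph1, Agap2 and Tsix, and those with the largest negative one were Cpn1, Keg1, Cyp2b13 and Plg, of which Cpn1, Cyp2b13 and Plg are expressed in liver. Their fitted values, from -16.06 for Cpn1 to 17.34 for Gm22009, involve groups at or near 0 counts, depend on the prior count and bound no fold, and the same holds for Perp. Rpph1 did not pass without vagus RiboTag 3 (edgeR BH-adjusted p = 0.0592, range over its alternatives 1.54e-11 to 0.0844), and Plg did not without sciatic RiboTag 2 (-6.49, 1, range 0.000228 to 1). The whole sciatic libraries with 19.9% mitochondrial ribosomal RNA enter every difference of this kind, and so does the removal of the epineurium from the sciatic nerve only.

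Across the 18997 tested genes, which are not independent replicates, the log2 fold changes of the 2 enrichments, which share no library, had a Pearson correlation of 0.403 ± 0.0471 (jackknife SD over libraries) and a Spearman correlation of 0.418. In both nerves 2366 genes rose, where independent lists would share 1201 on average, and 2563 fell, against 1805. Another 1520 passed in opposite directions, against 2947.

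Insig1, Cryab and Cldn14 did not pass with upper-quartile scaling, Insig1 and the ribosomal protein list not with library size alone, Insig1 not with DESeq2 size factors or protein-coding genes alone, and Pmp2, Rpph1 and Plg not with limma, where Perp was 4.43 and Cldn14 -5.46. The GC and length offset moved Insig1 to -0.14, Cryab to -0.15 and Itgb4 to -0.28 (not passing), Adamtsl1 to -5.71 and Rpl22 to 1.12 (passing), and ended the call of the long non-coding RNA list.

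**Figure D2:**
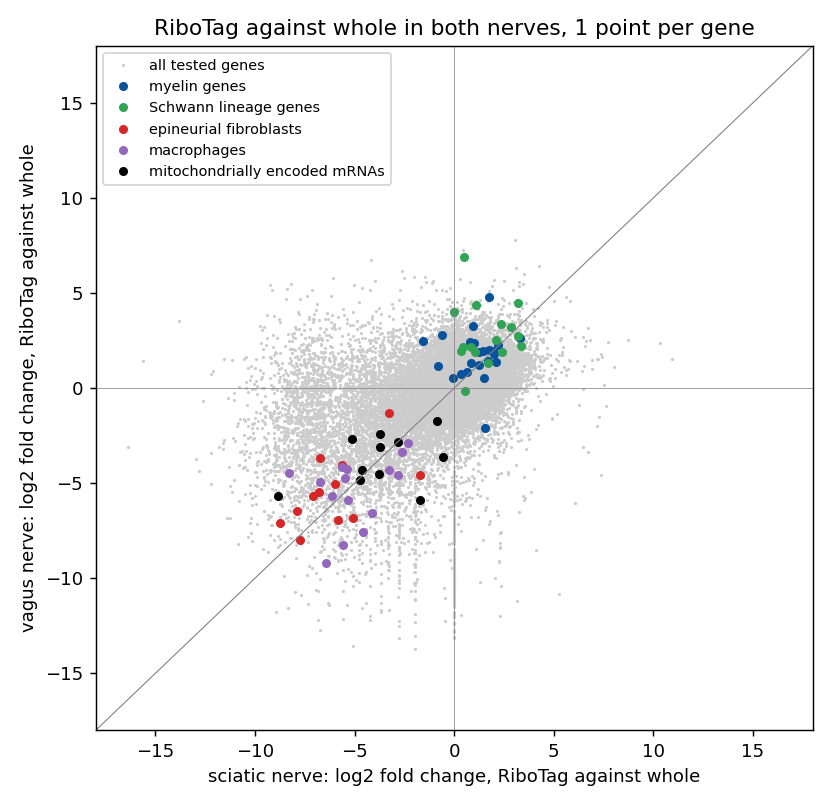
Log2 fold change of RiboTag against whole nerve in the sciatic nerve (horizontal axis) and in the vagus nerve (vertical axis), 1 point per tested gene, with myelin, Schwann lineage, epineurial fibroblast, macrophage and mitochondrially encoded genes in color. Across 18997 genes the Pearson correlation was 0.403, and all epineurial fibroblast and macrophage genes lie below 0 on both axes.

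Tagged ribosomes of the vagus nerve were then compared with those of the sciatic nerve. Mpz was lower in the vagus, at 5890.4 ± 1721 against 38576 ± 2127 CPM (mean ± SD, n = 3), a fall of 2.71 ± 0.36 on the log2 scale, and Pmp22 and Mbp fell by 2.51 ± 0.41 and 1.56 ± 0.33. Ncam1 was higher in the vagus, at 2286 ± 165 against 499.9 ± 87.8 CPM, a rise of 2.19 ± 0.39. Hmgcs1 was lower, at 239.7 ± 47.4 against 1679.7 ± 341 CPM, and Ifi27l2a, which interferon induces, was higher, at 1459.7 ± 516 against 13.1 ± 3.59 CPM. The edgeR BH-adjusted p was 9.92e-05 for Mpz, 0.000501 for Pmp22, 0.00272 for Mbp, 0.000951 for Ncam1, 6.67e-06 for Hmgcs1 and 7.09e-07 for Ifi27l2a. Of the tested genes 3566 rose and 2750 fell, against 4721 and 1933 with library size alone.

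Myelin genes fell in 21 of 23 cases and rose in 1, the connexin gene Gjc3 at 1.30 ± 0.21, with 22 passing adjusted over the list alone. The myelin median was -2.71 (camera BH-adjusted p = 2.44e-14, adjusted p = 0.335 with an estimated correlation). All 3 genes of the myelinating subtype fell, also adjusted over the list alone. The subtype median was -4.08 (camera BH-adjusted p = 6.04e-06, adjusted p = 0.155 with an estimated correlation), with Adamtsl1 at -3.69 ± 0.29, Pmp2 at -4.08 ± 0.54 and Cldn14 at -6.47 ± 1.02, or -11.47 without vagus RiboTag 3. Non-myelinating genes rose in 10 of 15 cases and fell in none, 13 adjusted over the list alone. The non-myelinating median was 1.23 (camera BH-adjusted p = 0.00487, adjusted p = 0.66 with an estimated correlation), with Matn2, a matrix protein, and Scn7a at 1.27 ± 0.38 and 0.90 ± 0.30. Scn7a did not pass without sciatic RiboTag 1, 2 or 3 or vagus RiboTag 1 or 3 (edgeR BH-adjusted p = 0.082, 0.0985, 0.0787, 0.0575 and 0.0963 in this order, range over its alternatives 0.0014 to 1), nor Matn2 without sciatic RiboTag 1 or 2 or vagus RiboTag 2 (0.072, 0.0597 and 0.0681, range 0.000266 to 0.072). The lineage genes Plp1 and Plekhb1 had 0.23 ± 0.34 and 0.01 ± 0.22 and did not pass, and Cryab fell by 1.42 ± 0.23. Rpl22 had 0.10 ± 0.18 and did not pass. Syt4, a synaptotagmin, went from 109 ± 6.84 to 0.898 ± 0.574 CPM, Uchl1, a ubiquitin hydrolase, from 225 ± 12.6 to 19.3 ± 3.74 CPM and Apod from 2327 ± 296 to 231 ± 77.2 CPM, and Crygs, a crystallin, had no count in the vagus and was at least 77.0-fold lower.

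Cholesterol synthesis genes fell in 23 of 24 cases and rose in none, 23 adjusted over the list alone. The cholesterol synthesis median was -1.83 (camera BH-adjusted p = 4.4e-20, adjusted p = 0.201 with an estimated correlation), with Dhcr24 at -3.21 ± 0.43 and Insig1 at -1.05 ± 0.21. Of 22 fatty acid and sphingolipid genes, 11 fell and 4 rose, and 16 passed adjusted over the list alone. The fatty acid median was -0.88 (camera BH-adjusted p = 5.62e-05, adjusted p = 0.462 with an estimated correlation). Those that rose were Srebf1, a transcription factor of lipid synthesis, the desaturases Scd1 and Fads2, and Fasn, fatty acid synthase, with Scd1 at 1.63 ± 0.38 and Fasn at 1.72 ± 0.45. Interferon response genes rose in 10 of 12 cases and fell in none, 10 adjusted over the list alone. The interferon median was 2.57 (camera BH-adjusted p = 6.83e-12, adjusted p = 0.261 with an estimated correlation), with Bst2 at 1.90 ± 0.23 and Ifit3 at 2.69 ± 0.31. Genes of cytosolic ribosomal proteins rose in 21 of 79 cases and fell in 1, Rps3, with 16 passing adjusted over the list alone. The ribosomal protein median was 0.47 (camera BH-adjusted p = 0.00806, adjusted p = 0.797 with an estimated correlation), and the list did not pass without vagus RiboTag 2 (adjusted p = 0.0521, range 0.000154 to 0.797). Hox genes of paralog groups 6 to 13 fell in 9 of 14 cases and rose in none, 11 adjusted over the list alone. The posterior Hox median was -4.74, or -3.46 with genes absent from a group at their bound (camera BH-adjusted p = 9.53e-05, adjusted p = 0.25 with an estimated correlation), with Hoxd8 at -2.92 ± 0.54 and Hoxc6, absent from the vagus, at least 11.3-fold lower.

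Of the 14 lists of other cell types, 5 were higher in vagus than in sciatic RiboTag libraries and 9 did not pass. All 12 skeletal muscle genes rose, also adjusted over the list alone. The muscle median was 8.06, or 6.58 with genes absent from a group at their bound (camera BH-adjusted p = 7e-10, adjusted p = 0.281 with an estimated correlation), with Tnnc2, a troponin, at 336 ± 296 against 0.885 ± 0.520 CPM, Acta1, skeletal actin, at 167 ± 104 against 0.202 ± 0.252 CPM and Myl1, a myosin light chain, at least 97.8-fold higher. Adipocyte genes rose in 9 of 11 cases, 9 adjusted over the list alone. The adipocyte median was 6.72, or 5.89 with genes absent from a group at their bound (camera BH-adjusted p = 1.43e-09, adjusted p = 0.261 with an estimated correlation), with Car3 at 483 ± 205 and Cfd, adipsin, at 159 ± 74.9 CPM in the vagus. Macrophage genes rose in 9 of 15 cases, 10 adjusted over the list alone. The macrophage median was 1.49 (camera BH-adjusted p = 0.00257, adjusted p = 0.439 with an estimated correlation). Lymphocyte genes rose in 9 of 12 cases, 10 adjusted over the list alone. The lymphocyte median was 6.34, or 1.47 with genes absent from a group at their bound (camera BH-adjusted p = 0.00122, adjusted p = 0.335 with an estimated correlation), and Igkc, an immunoglobulin chain of plasma cells, was at least 100.1-fold higher. Erythroid genes rose in 5 of 6 cases, 5 adjusted over the list alone. The erythroid median was 3.66 (camera BH-adjusted p = 1.81e-05, adjusted p = 0.335 with an estimated correlation), with Hbb-bs at 4.30 ± 0.49. Dcn, of fibroblasts, had 0.06 ± 0.22 and did not pass. The lists of endoneurial, perineurial, epineurial, endothelial, pericyte, mast cell, neuronal, chromaffin and thyroid genes did not pass (medians 0.38, 0.78, 1.84, -0.20, 0.50, -0.98, 0.15, 1.49 and 2.36). With genes absent from a group at their bound, the mast cell and chromaffin medians were -1.54 and 0.11. Perineurial genes passed without vagus whole 2 or vagus RiboTag 2 or 3 (camera BH-adjusted p = 0.0454, 0.0386 and 0.0423, range over its alternatives 0.0386 to 0.37). Epineurial genes passed without sciatic whole 1 or 2 or vagus RiboTag 2 (0.0339, 0.0334 and 0.0407, range 0.0334 to 0.668), and endothelial genes without vagus RiboTag 1 (0.0213, range 0.0213 to 0.877). Xist rose by 9.51 ± 0.92 between libraries that differed in sex-linked transcripts.

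With limma, Scn7a, Pmp2, Tnnc2, Acta1 and Xist did not pass. Without the filter on low counts, Scn7a, Matn2 and Fasn did not.

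The whole nerves were compared as background. The epineurium was removed from the sciatic nerve only, and effects of that step cannot be told apart from differences between the nerves. Mpz was lower in whole vagus, at 215 ± 113 against 11439 ± 2524 CPM in whole sciatic nerve (mean ± SD, n = 3), a fall of 5.73 ± 0.41 on the log2 scale, and Mbp and Pmp22 fell by 1.75 ± 0.33 and 2.48 ± 0.41. Ncam1 rose by 2.39 ± 0.40 to 375 ± 265 CPM. Hbb-bs rose from 17.2 ± 6.36 to 7728 ± 3732 CPM, Lyz2 from 113 ± 54.7 to 3347 ± 1664 CPM and Ifit3, an interferon-induced gene, from 16.4 ± 0.814 to 229 ± 79.0 CPM. The edgeR BH-adjusted p was 1.45e-07 for Mpz, 0.000468 for Mbp, 0.000169 for Pmp22, 0.000177 for Ncam1, 7.44e-08 for Hbb-bs, 8.59e-05 for Lyz2 and 6.37e-07 for Ifit3. Altogether 6338 genes rose and 5098 fell, against 5465 and 5886 with upper-quartile scaling.

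Myelin genes fell in 19 of 23 cases and rose in none, 19 adjusted over the list alone. The myelin median was -2.59 (camera BH-adjusted p = 5.94e-09, adjusted p = 0.439 with an estimated correlation), with Pmp2 at -8.16 ± 0.66. Of 16 lineage genes, 7 fell and 3 rose, Art3, Cdh19 and Sostdc1, with 10 passing adjusted over the list alone. The lineage median was -0.50 (camera BH-adjusted p = 0.0378, adjusted p = 0.797 with an estimated correlation). Rpl22 had -0.07 ± 0.18 and did not pass. Genes of cytosolic ribosomal proteins rose in 40 of 79 cases and fell in 6, Rpl38, Rps2, Rps15, Rps16, Rps21 and Uba52, with 46 passing adjusted over the list alone. The ribosomal protein median was 0.77 (camera BH-adjusted p = 0.000177, adjusted p = 0.732 with an estimated correlation), and -0.34 with the GC and length offset. All 12 interferon response genes rose, also adjusted over the list alone. The interferon median was 3.32 (camera BH-adjusted p = 1.68e-07, adjusted p = 0.335 with an estimated correlation), with Ifi27l2a at 3.37 ± 0.38 and Bst2 at 2.99 ± 0.25. Macrophage genes rose in 12 of 15 cases, 12 adjusted over the list alone. The macrophage median was 2.46 (camera BH-adjusted p = 0.00871, adjusted p = 0.462 with an estimated correlation). Lymphocyte genes rose in 11 of 12 cases, 11 adjusted over the list alone. The lymphocyte median was 5.93 (camera BH-adjusted p = 0.00014, adjusted p = 0.347 with an estimated correlation). All 6 erythroid genes rose, also adjusted over the list alone. The erythroid median was 9.08 (camera BH-adjusted p = 7.79e-08, adjusted p = 0.261 with an estimated correlation). Skeletal muscle genes rose in 11 of 12 cases, 11 adjusted over the list alone. The muscle median was 6.38 (camera BH-adjusted p = 0.00149, adjusted p = 0.559 with an estimated correlation).

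Neuronal genes fell in 9 of 14 cases, among them Snap25, a synaptic protein, at -2.93 ± 0.73 and Uchl1 at -2.61 ± 0.24, and rose in 2, Stmn2, a growth-associated protein, and Phox2b, a transcription factor of autonomic neurons, with 11 passing adjusted over the list alone. The neuronal median was -2.77 (camera BH-adjusted p = 0.0445, adjusted p = 0.601 with an estimated correlation). Hox genes of paralog groups 6 to 13 fell in 10 of 14 cases and rose in none, 10 adjusted over the list alone. The posterior Hox median was -6.96, or -5.55 with genes absent from a group at their bound (camera BH-adjusted p = 0.000303, adjusted p = 0.201 with an estimated correlation), with Hoxc6 at -6.96 ± 0.75. The pericyte and smooth muscle list did not pass (camera BH-adjusted p = 0.23), with 4 of 12 genes falling, among them Notch3 and Cspg4 by 3.35 ± 0.57 and 3.40 ± 0.29, and 1 rising. The liver genes Fabp1, Mat1a, Gc and Fgb had no count in whole sciatic nerve and were at least 2078, 1724, 1719 and 1553-fold higher in whole vagus, and all 4 belong to the hepatocyte list. Their levels varied between whole vagus libraries 1, 2 and 3, with Gc at 234, 76.3 and 823 CPM and Fgb at 201, 91.5 and 731 CPM, and without library 3 the fitted changes of Gc and Fgb were 14.12 and 14.03, against 15.48 and 15.34. Rmrp, Rpph1 and Scarna2, a Cajal body RNA, fell from 699.6 ± 337, 2092 ± 1588 and 222 ± 51.1 CPM to under 1 CPM, and Gm22009 was at least 846-fold lower.

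The lineage and neuronal lists lost their calls without vagus whole 2 (camera BH-adjusted p = 0.135 and 0.0689, ranges over their alternatives 0.00193 to 0.797 and 0.0105 to 0.601). The GC and length offset moved Notch3 to -0.24 and Cspg4 to -0.30 (not passing) and Ifi27l2a to 1.80, Bst2 to 1.83 and Rpl22 to -0.96 (passing), and ended the call of the ribosomal protein list.

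Of the 29 lists, 6 passed in none of the 5 comparisons. Injury and repair genes came nearest in RiboTag against whole vagus, where 5 of 10 rose, Sox2 by 5.62 ± 0.36, Mcam by 3.11 ± 0.38, Jun by 1.45 ± 0.19, Ngfr and Shh, with 5 passing adjusted over the list alone (camera BH-adjusted p = 0.0557). That list passed without any one of sciatic whole 1 to 3 or vagus whole 1 to 3 (camera BH-adjusted p = 0.0441, 0.032, 0.0359, 0.0325, 0.0311 and 0.0495 in this order, range over its alternatives 0.0311 to 0.313). Immediate early and heat shock genes came nearest in vagus against sciatic RiboTag, with 7 of 20 rising, 1 falling, 8 passing adjusted over the list alone and a camera BH-adjusted p = 0.132. Chromaffin genes had their smallest camera BH-adjusted p, 0.181, in RiboTag against whole vagus, with 4 of 6 falling. The 2 tested thyroid and parathyroid genes had 0.487 in vagus against sciatic RiboTag, and Hox genes of paralog groups 1 to 5 had 0.487 there, with 2 of 11 rising and 0 passing adjusted over the list alone. The 5 sex-linked genes had 0.278 in the difference of enrichment, and 0.0494 without sciatic whole 2 (range 0.0494 to 0.768). Of the 145 list tests, 56 passed with the preset correlation and none with an estimated one, where the smallest adjusted p was 0.155.

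Medians, means and tests of a list differed in sign in some cases that did not pass. Lineage genes in vagus against sciatic RiboTag had a median of 0.54, a mean of 0.17 and a test pointing down. In the same comparison sex-linked genes had a median of -1.74 and a mean of 0.72, and neuronal and pericyte genes had medians of 0.15 and 0.50 with tests pointing down. In RiboTag against whole sciatic nerve, injury and repair genes had a median of 0.22 and a mean of -0.66, and subtype genes a median of 0.04 with a test pointing down. Among the lists that passed, the cytosolic ribosomal proteins alone changed the sign of their median between scalings or with the GC and length offset. The median log2 fold change of all genes was -0.33, -0.13, 0.19, 0.18 and 0.15 in the 5 comparisons as ordered here, and it moved by over 0.1 to -0.53, -0.69 and -0.78 in RiboTag against whole sciatic nerve with DESeq2 size factors, upper-quartile scaling and library size alone. In RiboTag against whole vagus it was -0.38 with library size alone and -0.27 with the GC and length offset. With protein-coding genes alone it was -0.21 in RiboTag against whole sciatic nerve and 0.08 in the difference of enrichment. The difference of enrichment had 0.32, 0.55 and 0.39 with DESeq2 size factors, upper-quartile scaling and library size alone, vagus against sciatic RiboTag had 0.31 and 0.40 with the last 2 of them, and vagus against sciatic whole nerve had -0.09 with upper-quartile scaling. All 3 libraries of one group lay above all 3 of the other in CPM for each passing gene named by the rule in the 4 comparisons between groups, except Mbp, Pmp22 and Pmp2 in RiboTag against whole vagus. This tests nothing, since the genes of largest fold were chosen with that condition and the others because they passed, and chance alone gives 10% of genes such a separation.

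**Figure D3:**
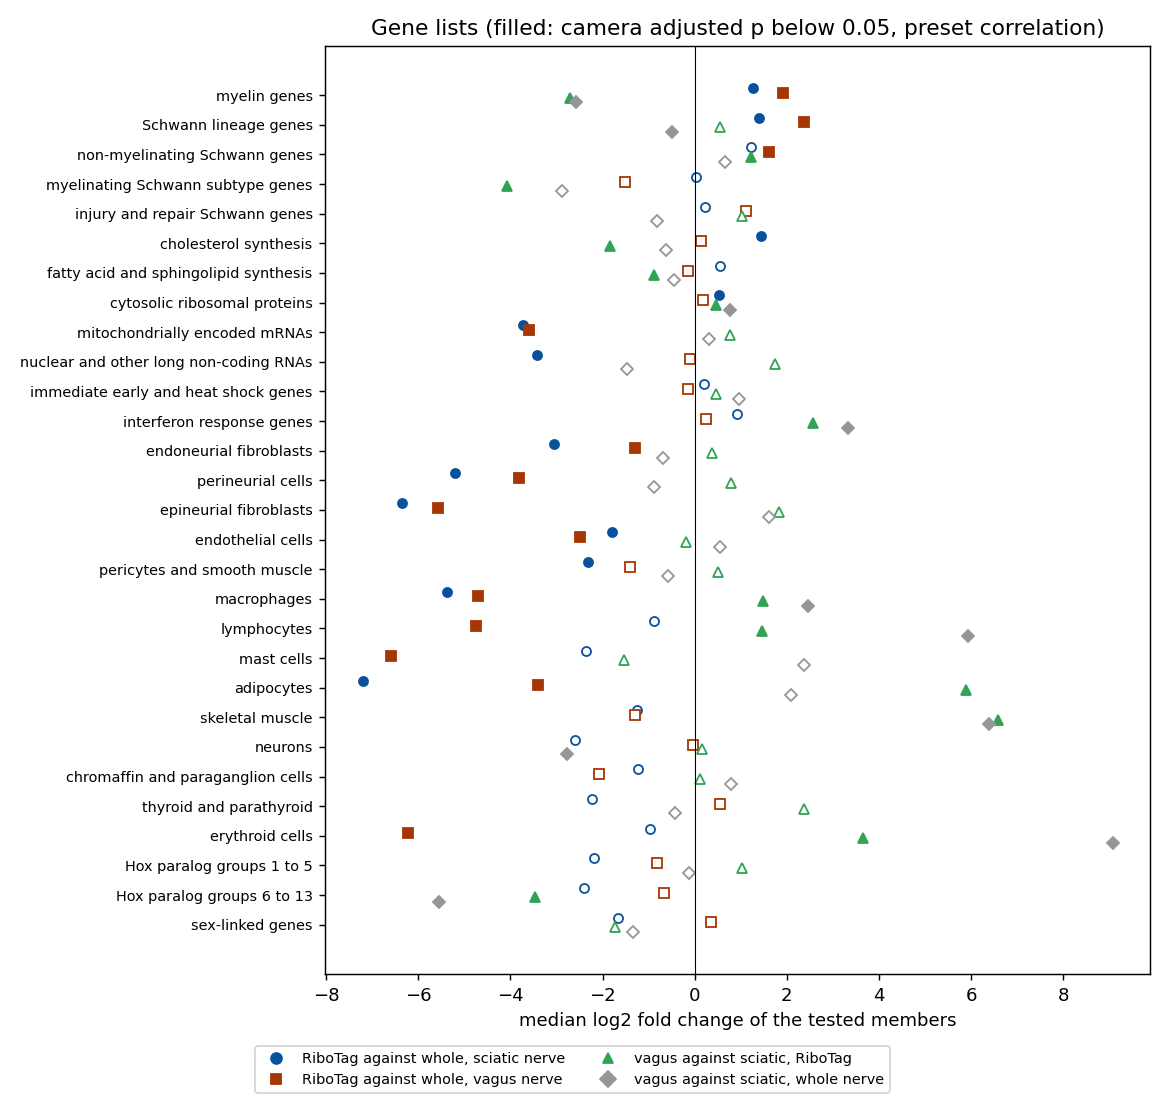
Median log2 fold change of each of the 29 gene lists in the 4 comparisons between groups, with genes absent from a group at their bound, where filled symbols mark a camera BH-adjusted p under 0.05 with the preset correlation. Cholesterol synthesis genes had a median of 1.43 in RiboTag against whole sciatic nerve and -1.83 in vagus against sciatic RiboTag.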

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

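Every result here was singled out because the difference of enrichment between the nerves was tested and passed. The tests of explanations below were chosen only after the result was seen, except the regrouping of libraries. That of the library preparation was chosen after RNAs without a poly(A) tail had been seen, on genes whose values had not. Values are the log2 difference, vagus minus sciatic enrichment, with 3 libraries in each of 4 groups.

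The difference for Mpz was 3.02, from 1.75 ± 0.35 in the sciatic to 4.78 ± 0.39 in the vagus nerve. With the GC and length offset it was 3.59 ± 0.50 (edgeR BH-adjusted p = 0.000119, range over its alternatives 6.61e-11 to 0.00119), which argues against bias by GC content or length. If tissue without myelin gene RNA diluted Schwann cell RNA in whole vagus libraries, other myelin genes should share the difference. Mpz lay 2.72 above the median of the other 22 (95% interval of that median -0.22 to 1.34, SD 1.59, highest Pmp2 at 4.08). That argues against such dilution as the whole cause and leaves a smaller part open. Some other tissue may itself hold RNA of other myelin genes, as hepatocytes do for Gjb1. Dilution by it would lower Mpz more than those genes, and stays open. Vagal Schwann cells might hold less Mpz RNA relative to other myelin RNAs, on their ribosomes too. Mpz should then lie below the other myelin genes in RiboTag libraries, but the gap there was -0.0854, against -3.20 in whole nerve. The cause of the whole nerve gap stays open.

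Rpph1 had 17.07 and the long non-coding RNA list 3.34, with high levels of RNAs without a poly(A) tail in whole sciatic libraries. If those libraries were prepared so as to keep such RNA, histone genes and small nuclear and nucleolar RNAs should also be lower in whole vagus, and the higher of their 2 medians was -1.12 (29 histone genes, median -3.52, and 33 small RNAs, whose 95% interval of -3.35 to 0.92 held 0). Histone genes went the way such a preparation predicts, but the interval of the small RNAs is too wide to decide, so it stays open. If it was used, it could move any gene in the comparisons that use whole sciatic libraries. By the design, nuclear RNA left behind by the pulldown cannot cause a gap between the whole libraries, which had no pulldown. The values only show that this gap exists, with a 95% interval of -4.80 to -1.84 for the histone median. The long non-coding median of -1.48 had one of -2.58 to -0.89. For the gap between RiboTag libraries, where the long non-coding median was 1.74 and the histone median 0.82, with 95% intervals of 0.25 to 2.37 and 0 to 2.61, a loss in the pulldown that differed between the nerves stays open.

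Schwann lineage genes had 0.93, Foxd3 6.36, Sox2 3.11, Mcam 2.72 and Scn7a 1.31, and in RiboTag libraries alone myelin genes were lower and non-myelinating genes higher in the vagus. RNA of some other cells was higher in vagus RiboTag libraries too. Medians were 8.06 for muscle, 6.72 for adipocyte and 6.34 for lymphocyte genes, or 6.58, 5.89 and 1.47 with genes absent from a group at their bound. They were 3.66 for erythroid and 1.49 for macrophage genes, and the remaining lists of other cell types did not pass. To lower myelin genes by their median, RNA of other cells would need to be 84.7% of the RNA. The 55 markers of other cells examined here, chosen for a high whole vagus level, stood at a median of 4.19% of that level (95% interval 1.91 to 9.47). Choosing markers by the level they are divided by can make this percent read low. It also varied by cell type, and muscle genes took 0.0802% of vagus RiboTag against 0.237% of whole vagus counts. The percent therefore cannot decide the question. The lineage median of 0.54 had an interval of -0.95 to 1.10 against -3.04 to -2.32 for myelin genes. Within the limit of such intervals, the lineage genes argue against RNA of other cells as the whole cause. The offset for GC content and length left the medians of myelin and non-myelinating genes 3.96 apart. A smaller share of myelinating cells among tagged cells should leave lineage genes between the lists of myelin and non-myelinating genes. The lineage median lay 3.25 above the myelin median, which fits, but nothing here counts cells. Less myelin RNA per tagged cell would give the same order, so this test cannot tell them apart.

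Rn7sk had 10.91, from -4.17 ± 0.38 in the sciatic to 6.73 ± 0.48 in the vagus nerve, and the larger share, in the vagus nerve, involves no whole sciatic library. Among the other genes with a positive difference, Adipoq had 8.45, Car3 4.42, Perp 7.17, Snap25 5.04, Col9a2 8.78, Lrrc4b 6.66, Xist 10.84, Pmp2 4.08, mt-Co1 2.42, Itgb4 2.37, Fasn 2.03, Malat1 1.42 and Jun 1.4. Among those with a negative one, Gm15564 had -9.42, Lars2 -7.95, Tpsb2 -5.15, Hbb-bs -4.51, Cldn14 -3.60, Adamtsl1 -3.23, Lyz2 -2.69, Apod -2.55, Egfl7 -1.80, Atf3 -1.71, Dcn -1.23, Cryab -1.10, Gsn -0.97, Uchl1 -0.93 and Insig1 -0.83. Adipoq, Perp, Rpph1 and Xist involve groups at or near 0 counts, and their fitted values depend on the prior count. Rn7sk in whole vagus libraries, and Pmp2 and Tpsb2 in vagus RiboTag libraries, were low too, so their values rest on few counts. List medians were 4.24 for adipocytes, 1.36 for perineurial cells, -0.38 for cytosolic ribosomal proteins, -1.13 for cholesterol synthesis and -5.34 for erythroid cells.

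Libraries were also regrouped to see how many genes pass by chance. Fits of the 6 compared libraries passed 11203 genes in RiboTag against whole sciatic nerve, 8848 in the vagus, 4209 in vagus against sciatic RiboTag and 13982 in the whole nerves. Of 10 splits of each 6 libraries, 1 gave as many, the real one, and the highest other count was 0, but 10 splits are too few for a share under 0.05. For the difference of enrichment, 60 splits of the 12 libraries were drawn, and 2 gave at least the real 8652 genes. The other of these gave 9968, and it kept all 4 groups whole and exchanged the nerves of the RiboTag groups. The 7 splits with the highest counts besides the real one, this one among them, kept the groups of one preparation whole.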

How the results depend on the processing

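The GC and length offset and the protein-coding fit were added after the data were seen, and no test in this part was chosen only after a result was seen otherwise. Of 4543 alternatives tried on 189 named results of genes, 4348 kept the direction and the side of the threshold, 135 fell short of it, 57 newly passed and 3 reversed. For 145 list results, 2176 of 2349 alternatives kept both, 80 fell short, 90 newly passed and 3 reversed. With the estimated correlation 0 lists passed and with fry 92, against 56. Fry tests a list against no change, whereas camera tests it against the other genes, so its count answers another question.

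Reversed with the GC and length offset were Rpl22 in RiboTag against whole sciatic nerve (-0.46, edgeR BH-adjusted p = 0.0334, range over its alternatives 0.0334 to 1), Itgb4 in the difference of enrichment (-0.28, 0.544, range 2.7e-10 to 0.544) and Adamtsl1 in vagus against sciatic whole nerve (1.82, 0.000122, range 0.000122 to 1). The cytosolic ribosomal protein list reversed with it in 3 comparisons (camera BH-adjusted p = 0.00653 in RiboTag against whole sciatic nerve, 0.026 in the difference of enrichment and 0.427 in vagus against sciatic whole nerve, ranges 0.000519 to 0.797, 0.00748 to 0.856 and 9.2e-06 to 0.731), and the cause was not tested.

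In vagus against sciatic RiboTag, 2267 genes rose with limma-voom and 2043 with the 6 libraries alone, against 3566, and 1542 fell with an absolute log2 fold change of at least 1, against 2750. The similarity of enrichment was 0.517 for genes with a mean of at least 10 CPM. The cause was not tested, apart from the stricter threshold and the fewer libraries. Other counts of passing genes stayed within 1.5 times their value under each alternative.

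With mitochondrially encoded genes left out of the total, which removes the ribosomal RNA that filled whole sciatic libraries, the difference in percent Mpz was 1.54 in RiboTag against whole sciatic nerve and -1.61 in vagus against sciatic whole nerve. That in percent ribosomal protein was -0.00406 in RiboTag against whole sciatic nerve, and those of the 10 most counted genes were 8.94 there and -1.67 in vagus against sciatic whole nerve.

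With each library left out in turn, 4493 to 5195 genes rose and 5714 to 7217 fell in RiboTag against whole sciatic nerve, 4247 to 4845 and 4256 to 5807 in the vagus, 3733 to 4899 and 3302 to 4164 in the difference of enrichment, 3078 to 4113 and 2076 to 2599 in vagus against sciatic RiboTag, and 5476 to 6778 and 4386 to 5810 in the whole nerves. The similarity ran from 0.368 to 0.420 and the lists that passed from 55 to 63. Mpz ran from 1.58 to 1.86, 4.62 to 5.38, 2.91 to 3.70, -2.80 to -2.49 and -6.31 to -5.55 in the same order. Differences in percent Mpz ran from 1.72 to 1.99 and 0.470 to 0.642 for RiboTag against whole in sciatic nerve and vagus, and from -2.69 to -2.50 and -1.43 to -1.15 for vagus against sciatic nerve in RiboTag and whole libraries. In this order of comparisons they ran from -1.32 to -1.26, -1.58 to -1.43, 0.0388 to 0.0792 and 0.205 to 0.358 for mitochondrial mRNA, from 0.0701 to 0.134, -0.384 to -0.241, 0.149 to 0.207 and 0.518 to 0.661 for ribosomal proteins, and from -8.94 to -7.27, 8.83 to 10.6, -1.52 to 0.278 and -19.1 to -18.1 for the 10 most counted genes. The range from -1.52 to 0.278 crossed 0 without sciatic RiboTag 2 and without vagus RiboTag 1.

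Whole and RiboTag vagus libraries share 3 index tags, but libraries with the same tag did not deviate together (correlations -0.00801, -0.0750 and -0.0884), and no library correlated best with its own tag, so the tags are not taken as pairs. With a replicate block by tag, 3587 genes rose and 4329 fell in RiboTag against whole vagus, and with the offset too, 3093 and 4329. Of 39 named gene results, 37 kept their call and Rpl22 (0.53, edgeR BH-adjusted p = 0.0733, range 0.00685 to 1) and Mbp (0.85, 0.125, range 0.00886 to 1) did not, and all 29 lists kept theirs.

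Depth was least in sciatic RiboTag 2, with 10109014 counts, and limits the genes given by bounds or with 1 to 3 counts.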

Other observations

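Of the tests in this part, those with the GC and length offset were chosen only after the result was seen. Atf3, a stress-induced transcription factor, rose by 2.01 ± 0.42 in RiboTag against whole sciatic nerve (edgeR BH-adjusted p = 0.00118), and Uchl1, known from neurons, by 2.21 ± 0.23 (edgeR BH-adjusted p = 2.49e-06), reaching 225 ± 12.6 CPM in RiboTag libraries. With the GC and length offset these were 1.24 and 0.97, which passed too.

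The hepatocyte list summed to 121, 107 and 86.4 CPM in whole sciatic libraries, between 11.1 and 15.1 in sciatic RiboTag, 10682, 2351 and 22739.5 in whole vagus and 76.5, 93.0 and 63.3 in vagus RiboTag libraries. Alb, serum albumin, reached 2019, 461 and 5852 CPM in the 3 whole vagus libraries. The mesothelium list summed to 249.5, 242 and 214 CPM in whole sciatic libraries, 299.7, 262 and 274 in sciatic RiboTag, 1874, 5310.4 and 2160.3 in whole vagus and 144, 96.0 and 123 in vagus RiboTag libraries.

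Xist was 291, 846 and 207 CPM in whole sciatic libraries, 184, 156 and 192 CPM in whole vagus and 129, 56.9 and 184 CPM in vagus RiboTag libraries. Ddx3y was 41.0, 0.155 and 57.4 CPM, 0.141, 58.4 and 0.611 CPM, and 20.8, 25.4 and 30.0 CPM in the same libraries. Both transcripts were present in whole sciatic libraries 1 and 3, whole vagus library 2 and all vagus RiboTag libraries, which points to RNA from animals of both sexes. Sciatic RiboTag libraries held Ddx3y and almost no Xist. Ddx3y was almost absent from whole sciatic library 2 and whole vagus libraries 1 and 3, so the mix of sexes varied between the other groups too. Every comparison may therefore carry a difference of sex, which cannot be told apart from the difference between the groups.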
